A study of Rattus norvegicus with 21 samples.

How the data were processed

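RNA of the right lung was measured in male Wistar rats after 1 intratracheal instillation of single-wall carbon nanotubes (SWCNT) or of vehicle, on 1-colour Agilent arrays labelled with Cy3. The 21 samples form 3 groups (vehicle control, low dose or L-SWCNT, high dose or H-SWCNT) with 1 sample per group on each of 7 days. The labels place 3 to 5 after the word replicate in each sample's source, and do not say whether this is an identifier or the number of arrays or animals behind the sample, while the series text gives 6 rats per group and day. What a sample pools is therefore not known. The high dose is 0.4 mg per rat, and the low dose is 0.1 mg in the series text and 0.2 mg in the protocols, so it is called the low dose here.

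Scanner images were read with Agilent Feature Extraction 10.7.3.1, per the submitters' processing notes. The deposited table holds 41103 rows of log2 values with 2 decimals. The base of the logarithm is not given in the sources used here. It was taken as 2 because a value of -9.97 is outside what base 10 allows on this kind of scanner, but the natural logarithm is not excluded, and folds would then be larger. The deposited log2 values are centred for each probe close to the control of the same day: the standard deviation over probes was 0.109 to 0.186 in control columns and 0.362 to 0.555 in treated columns. The level of a probe, its signal over background and any difference between the controls of different days are thereby lost. The difference between a treated sample and the control of the same day is kept, and all comparisons rest on it. No filter on dim probes could be set. The number of arrays limits the precision.

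The 41012 probes with IDs of the manufacturer's gene-probe form were tested, and the other 91 rows, among them 10 spike-in rows, were not. The files do not pair probes with genes. The gene table supplied, for assembly GRCr8, holds no array probe IDs, so no gene is named and no gene list was tested. Probe IDs are given sparingly instead. The rule set before the data were examined took up to 10 genes per direction among those past the threshold with the same sign on at least 6 of the 7 days (for a period, on all its days). Without gene names it was applied to probes and shortened to the 2 highest and 2 lowest over all days and to 1 in each direction for a period. Probes outside it are stated as such.

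Differences were fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend) on all 21 samples, with the day as a block and the group as a factor. A second model gave each group an effect in each of 3 periods (days 3 and 7, days 30 and 90, days 180, 365 and 754). A further model gave it a slope on log2 of the day. Benjamini-Hochberg adjusted p under 0.05 over all probes was the threshold. The days serve as replicates, so the residual holds the noise of single samples and change of the effect with time. A change with time shared by both doses is partly taken up by the day block, so the residual does not hold all of it. No test exists for a single day, where probes that differed by at least 1 were counted as a description. Samples of the same day deviated from their group means in the same direction, and the day block follows from the design. Correlations of these deviations across probes were 0.0801 to 0.300 between control and H-SWCNT, but 0.150 to 0.767 between the 2 doses. The fit takes 1 spread for all 3 groups. That spread can thus be too small for a dose against control and too large between the doses. Fitting only the 2 groups moved the probes at an unadjusted p under 0.05 from 8105 to 6172 for H-SWCNT against control. Between the doses they moved from 1352 to 2219. Because nothing says that the samples are separate animals, p-values measure the spread between these samples, which may be partly technical.

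The design and these tests were set before the data were examined, on the assumption that values keep a probe's level. They do not, so the intensity trend of eBayes runs over mean differences in place of intensities. It was kept as planned, and the fit without it is an alternative. On simulated data with 200 changed probes of 41012 and 5 random seeds, the fit over all days recovered on average 88% of H-SWCNT differences of 1 and 48% of those of 0.5. For days 180, 365 and 754 the planned fit recovered 80.4% of differences of 2 but 36% of those of 3, with 18% to 68% across seeds, against 92.8% and 98.8% without the trend. On days 3 and 7 it recovered 84.4% of differences of 3, against 98% without the trend. In these simulations the planned trend thus missed some of the largest differences within a period, and counts without it are given beside those that moved by more than 1.5 times. The simulated noise was independent between samples and equal in the groups, and changed probes were picked at random. In the data the doses deviated together, so the recovered shares need not hold there. For L-SWCNT differences of 2 the simulated recovery was 98.8%, yet 2 real probes at 2.04 and 2.03 did not pass.

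Sets of probes were also tested on days that had no part in choosing them. For each day, probes were ranked by limma's moderated statistic for H-SWCNT against control on the other 6 days. The 200 highest and the 200 lowest were then read on the day left out, as the median of the set minus the median of all probes. The mean of the 7 values was tested with a two-sided exact sign-flip permutation test, and its relation to log2 of the day with exact permutation of Pearson's and Spearman's coefficients. Benjamini-Hochberg adjustment ran over 12 tests for each of the sign-flip test, Pearson's and Spearman's coefficients, separately. The 12 also cover sets chosen on both doses together. This test was added after the data were seen. Its first form used probes past the threshold on the other 6 days. It was given up because it left no probe for days 7, 30, 90 and 180 and only 9 for day 3. Sets of 50, 100, 500 and 1000 probes were tried beside 200, and medians without subtracting that of all probes, also after the data were seen.

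Other alternatives were quantile normalization, centring of each column on its median, all rows, array weights, no day block, only the 2 groups compared, a threshold of 0.1, other forms of the time trend and each day left out. Because control columns had the smaller spread, quantile normalization widens them and narrows treated ones, so it is not a plain rescaling of these values. Shifting each column to the median of its spike-in rows, an F test between periods, the mean of both doses against control, the L-SWCNT periods and slope without the trend, and the L-SWCNT slope with each day left out were added after the data were seen. The array weights stopped before convergence in some models. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.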

Results

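Gene expression in the right lung of male Wistar rats was profiled on 3, 7, 30, 90, 180, 365 and 754 days after 1 intratracheal instillation of single-wall carbon nanotubes, which are hollow carbon fibres of nanometre diameter. Each day had 1 vehicle control sample (0.1% Triton X-100), 1 L-SWCNT sample and 1 H-SWCNT sample, which makes 7 samples per group. Values are log2 differences from the control of the same day over 41012 probes. The files do not pair probes with genes, so probes are given by ID.

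The comparison of H-SWCNT with control over all days asks which transcripts differed in the lung after the high dose whatever the time. In limma, 724 probes passed the threshold, of which 596 were higher with H-SWCNT and 128 lower. The higher probes had a median difference of 0.59, and 76 of them reached 1 or more. The lower probes had a median of -0.44, and 0 of them reached a fall of 1. Of the 596 higher probes, 390 were higher on all 7 days, and 100 of the 128 lower probes were lower on all 7. The same days served to call these probes, which by itself favours such agreement. At an unadjusted p under 0.05 there were 8105 probes, against 2051 expected by chance. The number past the threshold is fragile. It was 0 when only the H-SWCNT and control samples were fitted, 9 without day 3, 0 without any one of days 7, 30, 90 or 180, 577 without day 365 and 1690 without day 754, and those fits had 6172 to 8940 probes at an unadjusted p under 0.05. Quantile normalization, which gives control columns the same spread as treated ones, gave 367 probes, with 333 higher and 34 lower. Centring each column on its median gave 1492, with 1230 higher and 262 lower. Scaling to the spike-in rows gave 4493 probes, with 4479 higher and 14 lower, and raised the median of all probes from -0.02 to 0.13. That shift is the median of 10 rows that disagreed widely on some days. With H-SWCNT minus control they ran from -1.52 to 0.18 on day 30 and from -1.70 to 0.74 on day 180. All counts with this scaling share that limit. Without the day block the fit gave 54 probes.

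Among the probes past the threshold with the same sign on at least 6 of 7 days, the highest mean difference was that of A_44_P491796, at 2.68 ± 1.12 (SD over days, n = 7) with H-SWCNT, higher on 7 of 7 days (limma adjusted p = 0.0492). Its difference ran from 3.80 on day 30 to 0.85 on day 754. Probe A_42_P638620 was higher by 2.39 ± 1.31 (SD, n = 7; limma adjusted p = 0.0479), with 3.54 on day 90 and 0.22 on day 754. The lowest among them were A_44_P685354, at -0.98 ± 0.41 (SD, n = 7; limma adjusted p = 0.0300), and A_44_P906590, at -0.82 ± 0.42 (SD, n = 7; limma adjusted p = 0.0179), both lower on 7 of 7 days. Each of the 4 probes lost its call in 7 to 10 of 17 alternatives. These include the looser threshold, which is the same fit, and the mean of both doses, which is another comparison. All 4 probes kept their direction throughout, which is not separate evidence. With the same sign on 7 of 7 days, leaving out a day cannot reverse the mean. Several other alternatives leave the difference itself unchanged.

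**Figure D1:**
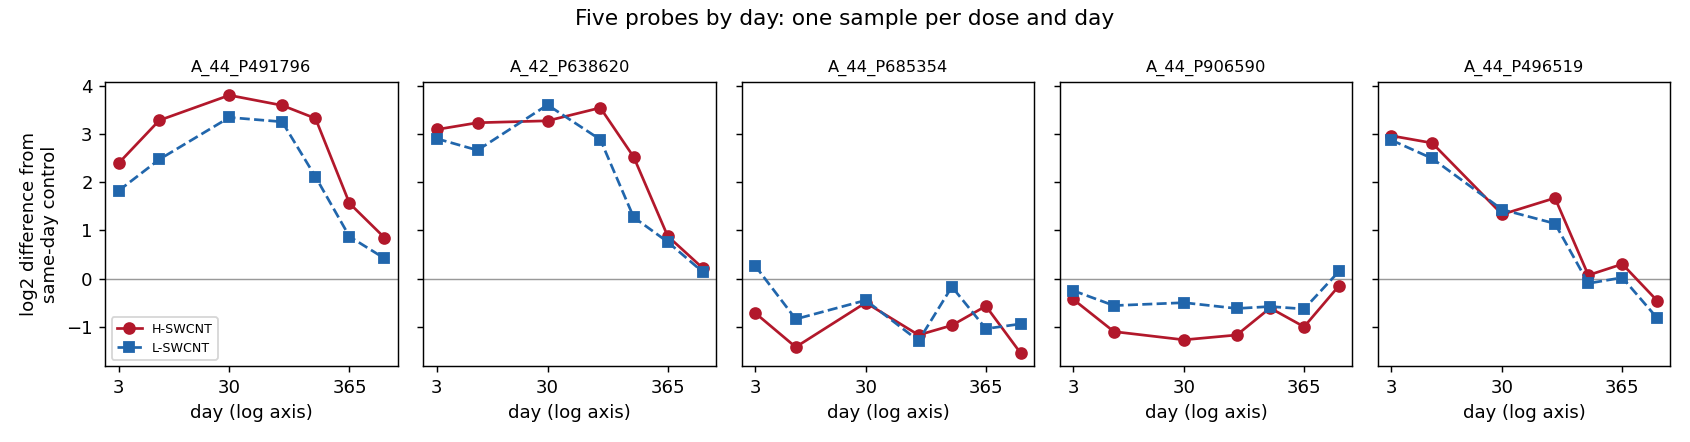
Log2 difference from the same-day control (vertical axis) against day on a log axis for 5 probes, with 1 sample per dose and day and no error bars. H-SWCNT is drawn as red circles and L-SWCNT as blue squares. Probe A_44_P491796 lies between 0.85 and 3.80 with H-SWCNT, and A_44_P496519 moves from 2.96 on day 3 to -0.46 on day 754.

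Probes chosen on 6 days were also higher on the day left out, relative to the median of all probes. The 200 probes most raised by H-SWCNT on the other days had a median above that of all probes on 7 of 7 days, by 0.61 ± 0.35 on average (SD, n = 7 days; exact sign-flip p = 0.0156, the smallest that 7 days allow, Benjamini-Hochberg adjusted p = 0.0312). The values were 0.48 on day 3, 0.99 on day 7, 0.985 on day 30, 0.69 on day 90, 0.755 on day 180, 0.25 on day 365 and 0.09 on day 754. As deposited, the day 754 median was only 0.02. On that day 52% of the 200 probes were above control, against 37.9% of all probes. The 200 most lowered probes averaged -0.14 ± 0.15 on the day left out (SD, n = 7; exact sign-flip p = 0.0781, adjusted p = 0.117), which did not pass. The sets were chosen on overlapping days, so the 7 values are not fully independent, and this test was added after the data were seen. The median of the higher set did not follow log2 of the day beyond chance (Pearson r = -0.58, exact permutation p = 0.18, adjusted p = 0.278; Spearman rho = -0.61, exact permutation p = 0.167, adjusted p = 0.222; 12 relations computed with each coefficient). Without days 3 and 7, the farthest from the median on the scale of log2 of the day, r was -0.94 over the remaining 5 days. No test was run on those 5 days. The size of r thus rests on which days are used.

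**Figure D2:**
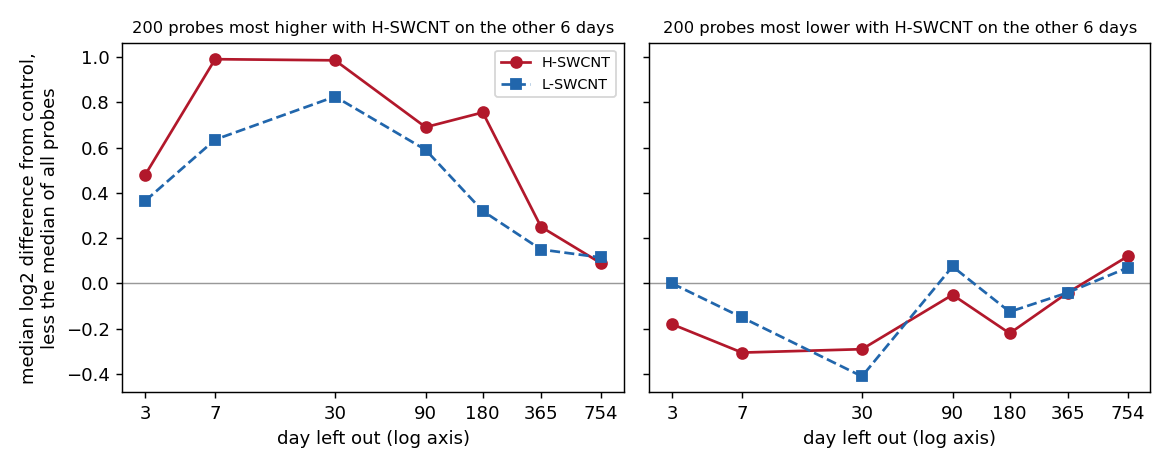
Median log2 difference from control of 200 probes, less the median of all probes (vertical axis), on the day that had no part in choosing them (horizontal log axis), for probes chosen as higher (left) and lower (right) with H-SWCNT on the other 6 days. Points are single days, red circles H-SWCNT and blue squares L-SWCNT. The higher set stays above 0 on all 7 days at both doses, from 0.99 on day 7 to 0.09 on day 754 with H-SWCNT. Without subtracting the median of all probes, the day 754 medians were 0.02 with H-SWCNT and 0.015 with L-SWCNT.

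The comparison of L-SWCNT with control asks the same of the low dose. In limma 0 probes passed (smallest adjusted p = 0.302), with 3835 at an unadjusted p under 0.05 against 2051 expected. Without the intensity trend 12 probes passed, all higher, and scaling to the spike-in rows gave 725. The probes A_44_P491796 and A_42_P638620 had L-SWCNT values of 2.04 and 2.03, and A_44_P685354 and A_44_P906590 of -0.64 and -0.43. Their limma adjusted p lay between 0.303 and 0.358. In the 200 probes most raised by H-SWCNT on the other days, the L-SWCNT median was above that of all probes on 7 of 7 days, by 0.43 ± 0.26 (SD, n = 7; exact sign-flip p = 0.0156, adjusted p = 0.0312). On day 754 that relative median was 0.115, but 0.015 as deposited, with 51% of the probes above control. L-SWCNT and H-SWCNT share the control of each day. Choosing the probes on other days removes the effect of that sharing on the choice, though not from the values of the day itself.

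Set directly against L-SWCNT, H-SWCNT differed in 0 probes by limma, with 1352 at an unadjusted p under 0.05 against 2051 expected. That fit takes its spread from all 3 groups. With only the samples of both doses, paired by day, 0 probes passed and 2219 had an unadjusted p under 0.05. In that paired fit A_44_P491796 was higher with H-SWCNT than with L-SWCNT on 7 of 7 days, by 0.64 (95% interval 0.17 to 1.12), and A_44_P906590 was lower on 7 of 7 days, at -0.39 (-0.67 to -0.11), but their limma adjusted p were 0.873 and 0.872. With all 3 groups in the fit the interval of A_44_P491796 was -0.74 to 2.03. The paired intervals of A_42_P638620 (-0.16 to 0.89) and A_44_P685354 (-0.85 to 0.15) included 0. These probes were named for their H-SWCNT difference from control, which favours a gap between the doses in the same direction. Relative to the median of all probes, the set of 200 probes raised on the other days was higher with H-SWCNT than with L-SWCNT by 0.17 ± 0.14 (SD, n = 7; exact sign-flip p = 0.0156, adjusted p = 0.0312). That relative difference was above 0 on 7 of 7 days, and was 0.41 on day 180 and 0.005 on day 754. As deposited, without subtracting the median of all probes, the difference was 0.16 ± 0.20 (SD, n = 7), above 0 on 6 of 7 days and -0.05 on day 30, and did not pass (exact sign-flip p = 0.0625), so the gap between doses depends on that centring.

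The periods ask when the lung differed. On days 3 and 7, 278 probes passed with H-SWCNT, 260 higher and 18 lower. The count was 464 without the intensity trend, 29 with quantile normalization, 133 with scaling to the spike-in rows and 2697 without the day block, of which 791 were lower. The highest was A_44_P452370, at 4.36 ± 0.04 (SD, n = 2 days; limma adjusted p = 0.0259), and the lowest A_44_P614539, at -1.26 ± 0.62 (SD, n = 2; limma adjusted p = 0.0466). On days 30 and 90, 338 probes passed, 162 higher and 176 lower. The count was 602 without the trend, 151 with quantile normalization, 780 with scaling to the spike-in rows and 3622 without the day block. Lower probes were the majority without the day block (2303), with array weights (371 higher, 553 lower) and at a threshold of 0.1 (657 and 965). The balance of directions there depended on scaling: centring each column on its median gave 443 higher and 131 lower, quantile normalization 110 and 41, and scaling to the spike-in rows 767 and 13. The highest was A_44_P175833, at 3.71 ± 1.70 (SD, n = 2; limma adjusted p = 0.0435), and the lowest A_44_P203401, at -1.60 ± 0.17 (SD, n = 2; limma adjusted p = 0.04998). Both counts were fragile: leaving out any single day left 0 to 68 probes on days 3 and 7, the highest without day 3, where 37 were higher and 31 lower, and 0 to 3 on days 30 and 90. Of the higher calls 53 were shared between these periods, against 1.03 expected of independent lists, and of the lower calls 6 against 0.0772. The periods share 1 estimate of each probe's spread, which by itself raises the overlap.

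On days 180, 365 and 754, 0 probes passed in limma (smallest adjusted p = 0.282), with 2955 at an unadjusted p under 0.05. Without the intensity trend 5 passed, without the day block 11, and with scaling to the spike-in rows 4791. In simulated data for this period the planned fit recovered 80.4% of differences of 2, 36% of those of 3 and 8.8% of those of 0.5, and the fit without the trend 92.8%, 98.8% and 14.8%. Small differences shared by the late days would thus mostly be missed. The 260 probes higher on days 3 and 7 had a median of 0.20 in the late period, and the 162 higher on days 30 and 90 a median of 0.34. The 18 probes lower on days 3 and 7 had a late median of 0.03, and the 176 lower on days 30 and 90 one of -0.03. With L-SWCNT, 1 probe passed on days 3 and 7 (A_44_P496519, 2.68 ± 0.27, SD, n = 2; limma adjusted p = 0.0207), 0 on days 30 and 90 (4751 at an unadjusted p under 0.05) and 0 in the late period (1603). Without the intensity trend, run for these after the data were seen, the counts were 23, 93 and 0.

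The slope on time asks whether the difference from control grew or shrank. With H-SWCNT 1 probe passed, A_44_P496519, with a change of -0.43 per doubling of time (limma adjusted p = 0.0467), and 5 passed without the intensity trend. It was also the 1 probe that passed with L-SWCNT, at -0.46 (limma adjusted p = 0.0242), and was named because of that count. It stood 2.96 above control on day 3 and 0.46 below it (-0.46) on day 754 with H-SWCNT. Leaving out any one day left 0 probes with H-SWCNT, as did centring each column on its median. With L-SWCNT it left 0 probes for 6 of the 7 days and 1 without day 90, and 3 passed without the intensity trend. The slopes share the same control samples, so their likeness is not independent evidence. An F test for any difference between the 3 periods called 0 probes in limma, with 4470 at an unadjusted p under 0.05. A difference between periods was therefore not shown for single probes, although the number of calls differed.

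Single days have no replicate. With H-SWCNT, 1949 probes differed from control by at least 1 on day 3, 2466 on day 7, 1585 on day 30, 1595 on day 90, 2501 on day 180, 1588 on day 365 and 1821 on day 754. As deposited, 15.1% of these were lower on day 365 and 89.7% on day 754, and with quantile normalization 43.9% and 63.5%. With L-SWCNT the counts were between 970 on day 365 and 2342 on day 7, and 95.4% were lower on day 754, or 65.0% with quantile normalization. Scaling to the spike-in rows turned the day 754 balance, to 15.2% lower with H-SWCNT and 33.1% with L-SWCNT.

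**Figure D3:**
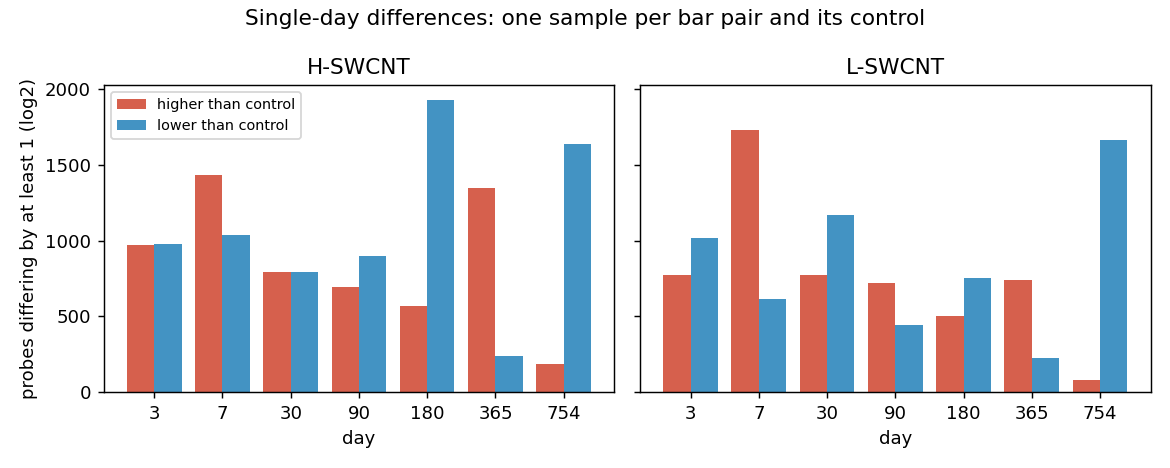
Number of probes that differed from the same-day control by at least 1 on the log2 scale (vertical axis, from 0) on each day (horizontal axis), higher in red and lower in blue, for H-SWCNT (left) and L-SWCNT (right). Each pair of bars compares 1 sample with 1 control sample and has no error bar. On day 754 there are 187 higher and 1634 lower probes with H-SWCNT.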

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

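The tests on spike-in rows, on covariance between doses, on days left out and on correlation between late days were chosen after the results were seen.

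On day 754 lower probes outnumbered higher ones at both doses. All 10 spike-in rows, which the comparisons do not use, were also below the control on that day, with a median of -0.655 for H-SWCNT (-0.71 to -0.21) and -0.57 for L-SWCNT (-0.67 to -0.25). On the other days these medians ran from -0.255 to 0.18 with H-SWCNT and from -0.22 to 0.30 with L-SWCNT. Control columns had spike-in medians of -0.035 to 0.04, but values are centred close to the control, so these are no yardstick. A shift of the whole column by its median, as tested in advance, is not enough, since after centring at least 85.6% of the differing probes were still lower. A larger shift stays open, because scaling to the spike-in rows, also a plain shift, left 15.2% and 33.1%. Quantile normalization, which also equalizes the spread of the columns, left 63.5% and 65.0%. Labelling or scaling that differed between treated and control arrays stays open and is consistent with the spike-in medians lying -0.47 or further from the median of all probes. A low spike-in median does not by itself go with lower probes, since on day 365 it lay at -0.27 from the median of all probes with H-SWCNT while 1348 probes were higher and 240 lower. A response of the old lung was not tested and stays open too.

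H-SWCNT and L-SWCNT differences of the same day correlated across probes at a mean r of 0.63, where simulated unchanged groups with a shared control gave 0.50, and the covariance was 0.128 against 0.0897 simulated. The simulation gave control and both doses the same spread, which by itself sets its r near 0.50. In the deposited values the spreads differed, so the simulated values cannot decide how much of the correlation is shared noise. Over all probes, noise of the shared control cannot be told apart from a common response: the covariance of one dose with the other on another day was 0.0264, with a jackknife standard error of 0.0145. For the 200 probes most raised by H-SWCNT on the other days, such noise alone is argued against by the mean L-SWCNT median of 0.43, above 0 on 7 of 7 days (exact sign-flip p = 0.0156). A common response of these probes to both doses is a hypothesis, found and tested on the same data.

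No probe passed on days 180, 365 and 754 with H-SWCNT. The test set in advance, the number of probes on days 180 and 365 without day 754, gave 0, but that fit also gave 0 on days 3 and 7, so it decided nothing about the day 754 arrays alone. A second test was then chosen with its value already known: days 180 and 365 correlated at -0.13 across all probes. Over all probes these days thus did not agree, and their balances were opposite, with 77.2% and 15.1% of the differing probes lower. In the 200 probes most raised on the other days, H-SWCNT medians relative to all probes were 0.755 on day 180, 0.25 on day 365 and 0.09 on day 754. A response of fewer probes, shared by days 180 and 365 and weakened by day 754, therefore stays open. Whether the late days differ from control in different probes stays open: their mean correlation of -0.029 runs over pairs that go both ways, with 0.18 between days 180 and 754 and -0.13 between days 365 and 754, against 0.36 between days 3 and 7.

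Other values stood out. With L-SWCNT, 1727 probes were higher by at least 1 on day 7, against 80 to 775 on the other days, and day 7 stayed highest with columns centred (2092) and with spike-in scaling (2296), but not with quantile normalization (887, where day 90 had 890). Between the doses, 1244 probes were higher with H-SWCNT on day 30, against 236 to 607 on the other days. These were 2 of 41 groups of 7 examined, where chance at 1 in 20 gives 2.05. The slope of A_44_P496519 on time passed at both doses, at -0.43 and -0.46 per doubling of time. Both are differences from the same control samples, and with H-SWCNT 0 probes passed when any day was left out.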

How the results depend on the processing

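Spike-in scaling, the F test, the mean of both doses and the sets of probes read on days left out, with their sizes, were chosen after seeing the data. Where no cause is given, the cause was not tested. The 724 probes of H-SWCNT over all days became 1959 at a threshold of 0.1, 367 with quantile normalization and 1492 with columns centred. They became 4493 with spike-in scaling and 0 with only the 2 groups. With each day left out they ranged from 0 to 1690 (9 without day 3, 0 without day 7, 30, 90 or 180, 577 without day 365, 1690 without day 754). The fit of only the 2 groups has fewer samples and also takes its spread from H-SWCNT and control alone. Which of these lowered the count was not tested. Array weights, all rows, no intensity trend and both doses together stayed within 1.5 times. The L-SWCNT count of 0 became 725 with spike-in scaling and 12 without the trend. The count of 0 between doses stayed 0 in all alternatives run. Without the day as a block, the counts were 54 for H-SWCNT over all days, 2697 on days 3 and 7, 3622 on days 30 and 90, 11 on the late days and 0 for the slope. The 278 probes of days 3 and 7 became 847 at 0.1, 29 with quantile normalization, 133 with spike-in scaling and 464 without the trend, and 0 to 68 with a day left out. The 338 of days 30 and 90 became 1622, 151, 780 and 602 in the same order, 574 with columns centred, 924 with array weights, and 0 to 3 with a day left out. The late 0 became 4791 with spike-in scaling, 5 without the trend, and 0 to 1 with a day left out. The 1 slope became 2 at 0.1, 2 with array weights, 5 without the trend, and 0 with columns centred, spike-in scaling, a linear or ranked day, the F test and each day left out (0 to 0). Spike-in scaling raised the median of all probes to 0.34 on the late days. The single-day total of 24718 stayed within 1.5 times under every scaling tried. Sets of 50 to 1000 probes gave means on the days left out of 0.71 to 0.43 with H-SWCNT, 0.47 to 0.30 with L-SWCNT and 0.23 to 0.13 between doses, all with an exact p of 0.0156 except 0.0312 between doses for 1000 probes. Without subtracting the median of all probes, the 200 probes gave 0.60 and 0.43 against control, both with an exact p of 0.0156, and 0.16 between doses with 0.0625. Not run, because the values hold no level and no gene names, were the trend in controls, gene lists, probes averaged per gene, the filter on dim probes and the linear offset. Signal over background is lost in these values, so no limit from it can be given.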

Other observations

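The correlations between days were looked at after the other results. Across probes, which are not independent replicates, H-SWCNT differences of days 3 to 180 correlated at a mean r of 0.29 over 10 pairs of days, and pairs with day 365 or 754 at a mean of 0.02 over 11 pairs. The split was chosen after looking, and the ranges overlap: the former went from 0.0856 to 0.395 and the latter from -0.13 to 0.195.

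Other splits of the samples were examined by swapping the labels of the groups within days. For H-SWCNT against control over all days, 2 of 64 splits gave as many probes as the real one, the real split with 724 included. The other one, which swapped day 754 alone, gave 1544 probes, more than the real labels, and no further split gave any. These splits cannot exclude chance, because the L-SWCNT samples stayed in the fit with their own labels. On each day L-SWCNT deviated with H-SWCNT more than with control, so a swap can by itself widen the residual and lower the count. Fitting only the 2 groups gave 0 probes with the real labels. Leaving day 754 out gave 1690 probes, and the 1274 higher ones among them had a median of -0.02 on day 754, close to 0. For L-SWCNT against control and for H-SWCNT against L-SWCNT the real count was 0, the highest other 1, and all 64 splits gave as many, as they must with a real count of 0, so these splits say nothing about chance. For H-SWCNT on days 180, 365 and 754 there are 4 splits, too few for a share under 0.05, with 0 for the real and 1 for the highest other, and all 4 gave as many.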
